A study of Arabidopsis thaliana with 6 samples.

How the data were processed

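Total RNA of 6 samples of Arabidopsis thaliana suspension cells, 3 induced with estrogen and 3 not, was labelled with biotin by the submitters and hybridised to Affymetrix AraGene arrays, per the labels' protocols. The deposited values are 1 number per probe and array, made by the authors with Affymetrix Expression Console 1.3, per the submitters' processing notes. The deposited values were read as log2 from their range of 0.30 to 14.05. The log base, the method that summarised probes, the background correction and whether the 6 arrays were normalized together are not given in the sources used here. The array medians differ between the runs of array numbers, at 6.15 and 6.08 against 5.41 to 5.55, so the values are not aligned to 1 distribution. No further normalization was applied for the main comparison.

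Groups were taken from the stimulation given in the labels. Replicate numbers only name the samples, in deposition order, and pair nothing. Array numbers in the sample titles form a run of 2 arrays, induced replicate 1 and uninduced replicate 1, and a run of 4 with the other arrays. The labels do not say what the numbers stand for. The run was used as a block in an alternative fit planned before the data were examined, and 14356 probes differed between the runs in that fit.

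Probes were named through the array's annotation, updated by gene identifier with a RefSeq gene table of assembly TAIR10.1. The build behind the probes was not given in the sources used here, so no coordinates are printed. Of 38408 probes, 16722 had 1 gene, 759 several and 20927 none in that annotation. The 16722 probes cover 16548 genes, and 148 of them had no entry in the gene table. Control probes were not separable from the others, so all 38408 were tested, where the plan had named the non-control probes. 7132 probes share all 6 values with at least 1 other probe, leaving 32879 distinct rows. Of 307 genes in the fixed lists, 44 were measured by name. VND1, the other secondary wall NAC genes and the lists for secondary wall cellulose, endodermis and jasmonate had no named probe and were not analysed here, so the planned check of the VND1 level and the comparison among the VND genes gave no value.

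Induced and uninduced arrays were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with no trend and no robust estimation. Benjamini-Hochberg adjustment ran over all probes, and an adjusted p under 0.05 was the threshold. Standard errors are the moderated ones of that fit, and SD is over the 3 arrays of a group. A gene with several probes is represented by the probe with the highest mean over all arrays. Gene lists of at least 3 measured genes were tested with camera at a preset correlation of 0.01 between genes, against the other named genes. Camera with an estimated correlation, and fry, ran beside it. The adjustment was made over the 5 testable fixed lists, separately over the 6 testable added lists, and not for the heat-response list, which stands alone. Families of at least 8 genes whose symbols share their first letters (at least 3) were tested with camera over 34 families. The text names the 12 largest rises and the 8 largest falls among changed genes whose arrays lie fully apart, up to 5 genes per list and up to 4 per family by size of change. GUT1, PRX47, PRX17 and ALPHA-VPE are outside that rule and are left out of the counts of named genes. Any other gene outside it is said to be so. No gene fell past the threshold, so no fall is named by the rule.

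The fixed lists, the tests and the alternative settings listed in the plan were written before the data were examined. The fixed lists cover secondary wall regulators, xylan, monolignol synthesis, lignin polymerisation, autolysis, wall patterning, primary wall, procambium, phloem, photosynthesis, cell cycle, heat shock, xenobiotic response and hypoxia besides those not analysed here. 7 lists (class III peroxidases, laccases, genes co-expressed with secondary wall synthesis, mitosis, DNA replication, protein folding in the endoplasmic reticulum and cytosolic ribosomal proteins) were added once the annotation and the array-level summaries had been seen, and before any comparison between groups. A heat-response list was written after some of its members had been seen among the largest falls.

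Alternatives were a variance trend with robust estimation, quantile normalization, centring on the array median, leaving out the 25% of probes with the lowest mean, array weights, the run as a block, leaving out each array, other thresholds, an unmoderated test, and other settings of the list tests. The run of 4 arrays alone, combined settings, single-gene probes only and identical rows counted once were added after the data were seen.

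The comparison was tested on simulated data with the levels, run differences and residual spread of the 38408 probes and 200 changed probes, over 10 simulations of the induced against uninduced comparison. Without a block, a log2 change of 4 was found at 70.3% of probes that rose and 73.0% that fell, a change of 2 at 39.7% and 38.2%, and a change of 1 at 0.588% and 0.909%. With the run as a block these shares were 90.6% and 90.9%, 75.0% and 69.4%, and 40.9% and 43.0%. With nothing changed, 0 probes were called in either fit. The share of probes whose simulated groups lay fully apart with nothing changed was counted after the results were seen. Camera found a list of 25 genes shifted by -0.5 in all 10 simulations over 16548 genes, and 8 of 190 unshifted lists had an unadjusted p under 0.05. The simulated genes are independent of each other, so this says nothing of correlated lists. Figures were drawn with matplotlib 3.10.9.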

Results

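Gene expression was measured on Affymetrix AraGene arrays in a suspension culture of Arabidopsis thaliana whose cells carry an estrogen-inducible VND1-GFP construct. VND1 (VASCULAR-RELATED NAC-DOMAIN1) belongs to a family of NAC transcription factors that switch on the differentiation of xylem vessel elements, the dead, lignified cells that conduct water. The cells grew in the dark at 23 °C on a shaker at 124 rpm. 3 arrays hold RNA from cells given 5 µM estrogen for 24 h (induced), and 3 hold RNA from cells cultured for the same 24 h without estrogen (uninduced). The comparison asks which genes change when VND1 is induced with estrogen. No estrogen-treated cells without the construct are among the arrays, so effects of VND1, estrogen and handling of the cultures cannot be told apart. The labels do not say that the 3 samples of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

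Each array gave a value for 38408 probes on a log2 scale from 0.30 to 14.05. Array numbers in the sample titles fall into a run of 2 arrays (1 induced, 1 uninduced) and a run of 4 (2 and 2), and these runs differed in overall level. The median probe lay at 6.15 and 6.08 on the 2 arrays of the first run and between 5.41 and 5.55 on the other 4. The first principal component held 60.8% of the variance and separated the runs, while the second separated induced from uninduced arrays in both runs. Pearson correlations across probes between arrays ranged from 0.955 to 0.984. Both groups are present in each run, so every gene list test below is also given with the run as a block and as the median change within each run. The number of arrays limits the precision. VND1 itself, the other secondary wall NAC genes and the secondary wall cellulose synthase genes were not analysed here, because no probe was paired with them in the annotation used.

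After induction 4 of 7 measured xylan genes, 3 of 8 lignin polymerisation genes and 3 of 7 autolysis genes rose, and no gene of these lists fell. Of the named genes, AT1G70500, a predicted polygalacturonase (a pectin-degrading enzyme), rose most. Its level was 11.84 ± 0.09 (SD, n = 3) in induced cells and 4.21 ± 0.43 (SD, n = 3) in uninduced cells, a 198-fold rise. AT5G40020, which codes for a thaumatin-like protein, rose 113-fold, and PRX66 (AT5G51890), a class III peroxidase, rose 50.0-fold. In all, 205 of the 38408 probes were higher in induced cells and 0 were lower (limma, Benjamini-Hochberg adjusted p under 0.05). At an unadjusted p under 0.05, limma gave 1151 higher and 1053 lower. All 205 probes rose by at least 2-fold, 128 by at least 4-fold and 49 by at least 16-fold, with a median log2 change of 2.55. On each of the 205 probes all 3 induced arrays lay above all 3 uninduced arrays. A rise within the run of 2 arrays follows from this and is no separate check. Complete separation in either direction held for 13.5% of all probes, against 10% by chance for exchangeable arrays. These arrays are not exchangeable, as the runs differ, and simulated arrays with the same run differences and no induced change gave 2.83% to 3.12% over 10 simulations. The simulated probes vary independently, so differences that many probes of an array share are missing from that range. It therefore cannot tell how far such differences account for the 13.5%. Of the 205 probes, 94 were paired with 1 gene, 4 with several genes and 107 with none.

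With the array-number run as a block, 381 probes were higher and 13 lower, and 204 of the 205 were among those changed. In the run of 4 arrays alone, 140 were higher and 3 lower, and 116 of the 205 were among those changed. Moderation of the variance with a trend and robust estimation gave 351 higher and 14 lower, and 802 higher and 423 lower with the run as a block as well. The count of rises fell to 86 without induced replicate 1, 61 without induced replicate 2, 56 without induced replicate 3, 59 without uninduced replicate 2 and 62 without uninduced replicate 3, and was 154 without uninduced replicate 1.

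**Figure D1:**
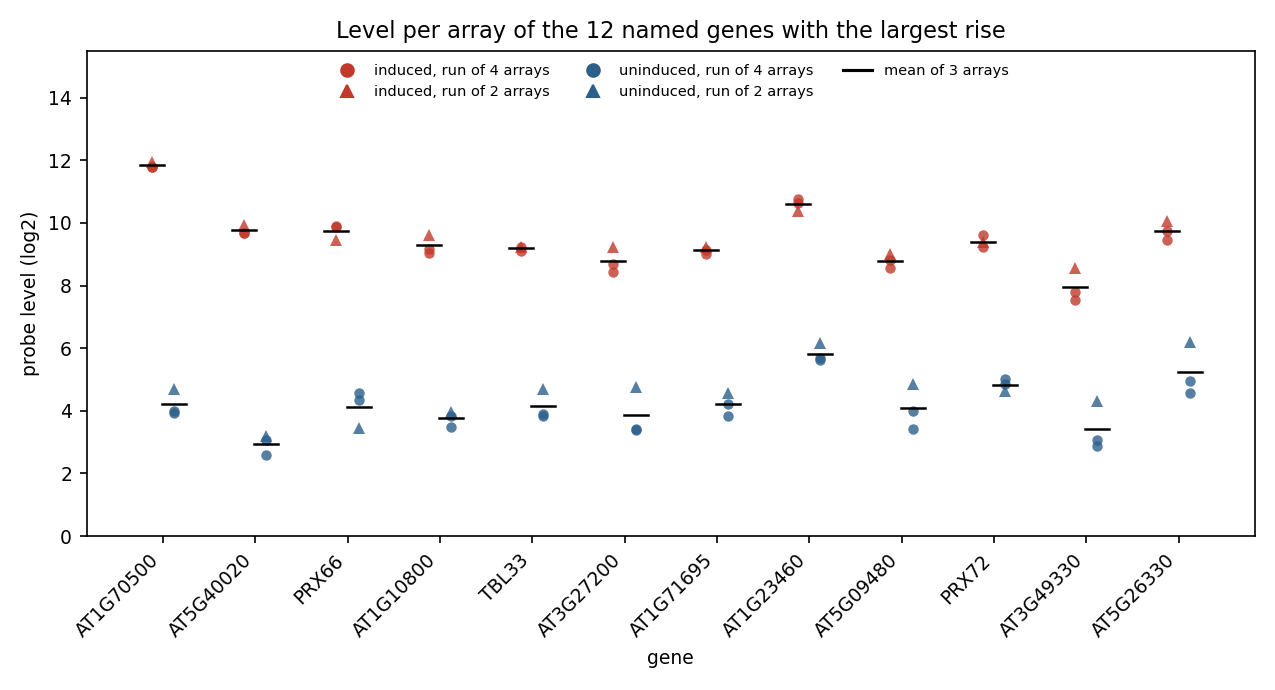
Probe level on a log2 scale (vertical axis) on each of the 6 arrays for the 12 named genes with the largest rise (horizontal axis). Red symbols are induced arrays, blue symbols uninduced arrays, triangles the run of 2 arrays, circles the run of 4, and bars the mean of 3 arrays; every induced array lies above every uninduced one, from a 198-fold difference at AT1G70500 to a 22.8-fold difference at AT5G26330.

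2 of the 12 largest rises, AT1G70500 and AT1G23460, are predicted polygalacturonases, and the latter rose by 4.76 ± 0.21 on the log2 scale (SE, adjusted p = 0.00120). 3 of the 12 are class III peroxidases, enzymes that can oxidise lignin precursors in the wall. PRX66 rose by 5.64 ± 0.33, AT1G71695 by 4.91 ± 0.21 and PRX72 (AT5G66390) by 4.58 ± 0.17. AT3G27200 and AT5G26330 code for cupredoxins, small blue copper proteins, and rose 30.4-fold and 22.8-fold. TBL33, a xylan acetyltransferase, rose 33.0-fold. AT5G09480, which codes for a proline-rich protein, rose 26.1-fold, AT3G49330, a predicted invertase and pectin methylesterase inhibitor, rose 23.3-fold, and AT1G10800 rose 45.8-fold. Adjusted p over the 12 genes ranged from 4.7e-04 to 0.0264. Uninduced levels of these genes lay between 2.95 and 5.83, against array medians of 5.48 to 6.08 on the uninduced arrays. Those of AT5G40020, 2.60 to 3.18, were close to the 5th percentile of the same arrays (2.42 to 3.12). Background was not estimated here, so the change of any gene whose uninduced level was background is a lower bound, and the order of the largest folds is uncertain to that extent. IRX15, DMP4 and AT1G09440, given below, also had uninduced values near those percentiles in the run of 4 (down to 2.51, 2.63 and 2.33). The calls of AT3G27200, AT5G09480, AT3G49330 and AT5G26330 were lost for 5, 4, 5 and 5 of the 6 arrays left out (highest adjusted p 0.122, 0.0997, 0.174 and 0.160). The other 8 genes passed whichever array was left out.

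Xylan is the main hemicellulose of the secondary wall, and 7 of the 27 genes listed for its synthesis and acetylation were measured, of which 4 rose, 0 fell and 3 did not pass the test. TBL33 and TBL34, which acetylate xylan, rose by 5.04 ± 0.26 and 3.21 ± 0.29 on the log2 scale (SE). GUT2 (also IRX10), a xylan xylosyltransferase, rose by 2.78 ± 0.16, from a level of 7.81 ± 0.20 to 10.59 ± 0.13 (SD, n = 3). IRX15-L, which is needed for normal xylan, rose by 2.87 ± 0.30. Its paralogue IRX15 gave 2.66 ± 0.52 (adjusted p = 0.255) and TBL31 2.49 ± 0.39 (adjusted p = 0.119), and both were also higher when adjusted over the list alone, which gave 6 higher and 0 lower. The GUT2 paralogue GUT1 differed by -0.12 ± 0.13. The list's median change was 2.78 (2.14 in the run of 2 arrays, 3.23 in the run of 4). It was higher than other genes by camera (adjusted p = 6.5e-16 over 5 fixed lists; 3.5e-09 with the run as a block). With an estimated correlation the adjusted p was 0.0311, and 0.0920 with the block as well. The calls of TBL34 and IRX15-L were each lost for 5 of the 6 arrays left out (adjusted p up to 0.131 and 0.180). That of IRX15-L was also lost in the run of 4 alone (adjusted p = 0.0753).

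The measured lignin genes gave a divided picture. Of the 16 genes of the lignin polymerisation list, which holds laccases and peroxidases, 8 were measured. Of these, 3 rose, 0 fell and 5 did not pass the test. PRX66 and PRX72 rose as above and PRX52 rose by 1.49 ± 0.15 (SE, adjusted p = 0.0228). LAC16, a laccase, gave 0.53 ± 0.30, and PRX71, PRX47 and PRX17 lay between -0.25 and -0.20. The count was also 3 higher and 0 lower when adjusted over the list alone. The median change was 0.29 (0.16 and 0.38 in the runs of 2 and 4), and camera gave an adjusted p of 7.8e-05 (0.00386 with the block). The adjusted p with an estimated correlation was 0.0311, and 0.0920 with the block. The PRX52 call was lost whichever array was left out (adjusted p up to 0.184) and in the run of 4 alone (adjusted p = 0.0588). In monolignol synthesis, 2 of 19 listed genes were measured. HCT, which makes the shikimate esters on the way to lignin monomers, rose 3.01-fold from 8.78 ± 0.04 to 10.37 ± 0.14 (SD, n = 3). Its adjusted p was 0.0119, and the call was lost for 5 of the 6 arrays left out (adjusted p up to 0.114). CCR2, a cinnamoyl-CoA reductase, gave 0.21 ± 0.19 (SE). Over these 2 genes, adjusted over the list alone, 1 was higher and 0 lower.

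Vessel elements die by autolysis, and 7 of the 17 genes listed for it were measured, of which 3 rose, 0 fell and 4 did not pass the test. DMP4 and EXI1, transcripts that mark developmental cell death, rose by 4.18 ± 0.52 and 2.69 ± 0.30 on the log2 scale (SE, adjusted p = 0.0491 and 0.033). The aspartic protease gene PASPA3, another such marker, rose by 1.12 ± 0.13 (adjusted p = 0.0429). The serine carboxypeptidase gene scpl48 gave 0.75 ± 0.11 (adjusted p = 0.105, and 0.0318 with the run as a block, where 4 genes of the list were called), from an already high uninduced level of 12.33. Of the vacuolar processing enzymes, proteases of the vacuole, GAMMA-VPE gave 0.44 ± 0.18 and ALPHA-VPE -0.15 ± 0.27. There were 4 higher and 0 lower when adjusted over the list alone, and 5 with the run as a block, where GAMMA-VPE joined them (adjusted p = 0.0146). The median change was 0.75 (0.79 and 0.73 in the runs of 2 and 4), with a camera adjusted p of 8.8e-09 (1.2e-06 with the block). The adjusted p with an estimated correlation was 0.0311, and 0.0697 with the block. The DMP4 and EXI1 calls were each lost for 5 of the 6 arrays left out (adjusted p up to 0.294 and 0.213). That of PASPA3 was lost whichever array was left out (adjusted p up to 0.278). The PASPA3 call was also lost after centring each array on its median (adjusted p = 0.275), after quantile normalization (adjusted p = 0.119) and in the run of 4 alone (adjusted p = 0.153).

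The last 2 fixed lists with enough measured genes showed small changes, with 3 of 23 primary wall and 3 of 29 cell cycle genes measured. All 3 measured primary wall genes were positive but none passed the test, with CSLC04, a xyloglucan glucan synthase, at 0.43 ± 0.13 (SE), the expansin EXPA4 at 0.36 ± 0.14 and COB at 0.17 ± 0.14. As a list they were higher (median 0.36, 0.49 and 0.26 in the runs; camera adjusted p = 0.00164, 0.00745 with the block, 0.0394 with an estimated correlation, and 0.147 with both). The adjusted p was 0.0769 without uninduced replicate 1 and 0.0611 after centring each array. All 3 measured cell cycle genes were negative, namely the mitotic kinases AUR1 (-0.35 ± 0.17) and AUR2 (-0.36 ± 0.14) and PRL (-0.33 ± 0.14), a subunit of the replicative helicase. As a list they were lower (median -0.35, -0.25 and -0.40 in the runs; camera adjusted p = 0.00165, 0.00745 with the block), but the adjusted p was 0.0620 with an estimated correlation and 0.0920 with the block as well. Adjusted over the list alone, 0 genes of either list changed. With the run as a block as well, 2 primary wall genes were higher (CSLC04, adjusted p = 0.00998, and EXPA4, 0.0302) and 2 cell cycle genes lower (AUR2 and PRL, adjusted p = 0.0316 for each).

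**Figure D2:**
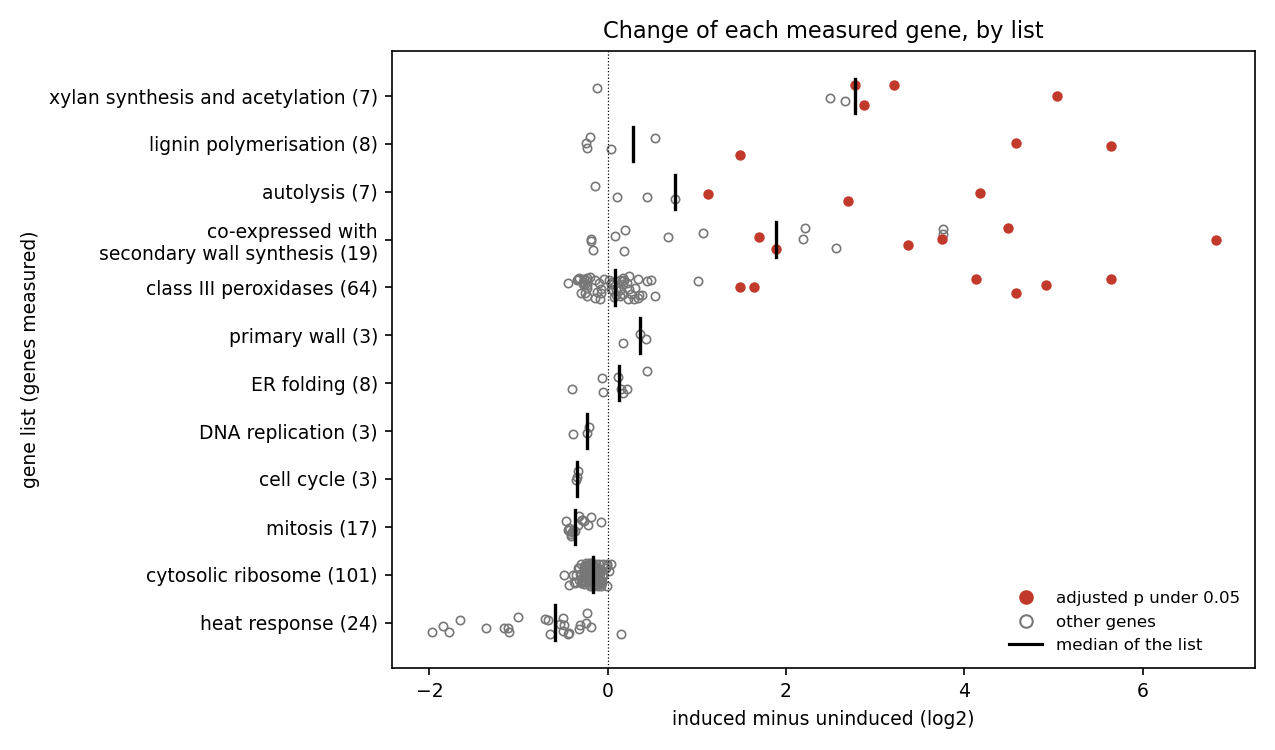
Change of each measured gene, induced minus uninduced on a log2 scale (horizontal axis), in each gene list (vertical axis, with the number of genes measured). Filled red points passed an adjusted p of 0.05 over all probes, open points did not, and bars are list medians; the 7 xylan genes have a median of 2.78, while the 17 mitosis genes all lie below 0 with a median of -0.37.

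Other fixed lists had 1 or 2 measured genes each and were not tested as lists. The zinc finger gene C3H14, a regulator of secondary wall synthesis, gave 1.07 ± 0.21 (SE, adjusted p = 0.237). It was the only measured gene of its list, so adjusting over the list alone left its unadjusted limma p of 0.00234. In microtubule-based wall patterning, KINESIN-13A gave 0.27 ± 0.12 and COG2 0.22 ± 0.12. For other cell types, the procambium genes LHW and PHV gave -0.14 ± 0.13 and 0.13 ± 0.14, the phloem genes OPS and SAPL 0.20 ± 0.16 and 0.04 ± 0.51, and the photosynthesis gene RCA 0.10 ± 0.35. The endodermis markers and the jasmonate list were not analysed here. The xenobiotic response genes GSTU25 and AER gave 0.23 ± 0.13 and -0.01 ± 0.26. Of the stress genes, ROF2 and ATHSP22.0 of the heat shock list gave -1.17 ± 0.41 and -0.19 ± 0.14, and HUP26 and HRA1 of the hypoxia list -0.94 ± 0.51 and -0.67 ± 0.40. List medians in the runs of 2 and 4 arrays were -1.14 and -0.44 for heat shock and -1.92 and -0.25 for hypoxia, the run of 2 having 1 array per group. None of these genes passed the test. Over each list alone only C3H14 lay under the threshold, where there was nothing to adjust. With the run as a block ROF2 did as well (adjusted p = 0.0223).

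Lists added after the annotation was seen, and before the groups were compared, covered more measured genes. Of 19 measured genes known to be expressed together with the secondary wall cellulose synthases, 6 rose, 0 fell and 13 did not pass the test. AT5G40020 rose by 6.82 ± 0.20 on the log2 scale (SE), AT5G60720 by 4.49 ± 0.19 and AT1G63520 by 3.75 ± 0.27, while AT1G09440 gave 3.77 ± 0.59 (adjusted p = 0.121) and AT4G08160, a predicted xylanase, 3.76 ± 0.52 (adjusted p = 0.0744). Adjusted over the list alone, 12 were higher and 0 lower (13 and 0 with the run as a block). With the block 10 passed over all probes, among them AT1G09440 (adjusted p = 0.0171) and AT4G08160 (0.0354). The median change was 1.89 (1.70 and 1.95 in the runs), with a camera adjusted p of 9.5e-21 over 6 added lists (5.5e-15 with the block). The adjusted p with an estimated correlation was 0.129, and 0.0189 with the block. Of 64 measured class III peroxidases, 6 rose, 0 fell and 58 did not pass the test. Besides PRX66, AT1G71695, PRX72 and PRX52, these were AT5G15180 (4.14 ± 0.13) and AT4G36430 (1.64 ± 0.12). Adjusted over the list alone, 7 were higher and 0 lower. The median change was 0.08 (0.14 and 0.07 in the runs), with a camera adjusted p of 0.00337 (0.0219 with the block and 0.0571 in the run of 4 alone). The adjusted p with an estimated correlation was 0.474, and 0.196 with the block. The calls of AT1G63520 and AT4G36430 were each lost for 4 of the 6 arrays left out (adjusted p up to 0.0775 and 0.0953). That of AT1G63520 was also lost in the run of 4 alone (adjusted p = 0.0809). 7 of the 8 lignin polymerisation genes belong to this list too.

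Genes of cell division and protein synthesis lay slightly lower in induced cells, with no single gene passing the test. All 17 measured mitosis genes were negative (median -0.37, -0.32 and -0.39 in the runs), among them the kinesin AT5G60930 (-0.47 ± 0.20, SE), BUBR1 of the spindle checkpoint (-0.43 ± 0.16) and the kinesin AT3G44050 (-0.43 ± 0.12). Adjusted over the list alone, 0 were lower, and 12 with the run as a block. As a list they were lower by camera (adjusted p = 5.0e-11, 8.4e-10 with the block), but the adjusted p was 0.129 with an estimated correlation and 0.0585 with the block as well. Of 101 measured cytosolic ribosomal protein genes, 99 were negative (median -0.17, -0.13 and -0.19 in the runs), with 0 lower when adjusted over the list alone. As a list they were lower (adjusted p = 7.5e-11, 1.3e-11 with the block), but the adjusted p was 0.294 with an estimated correlation and 0.172 with the block as well. The 3 DNA replication genes PSF2 (-0.39 ± 0.20), POLD3 (-0.23 ± 0.13) and POLA3 (-0.21 ± 0.16) had a median of -0.23 (-0.20 and -0.27 in the runs) and were lower as a list (adjusted p = 0.0194, 0.0327 with the block). That adjusted p was 0.294 with an estimated correlation and 0.172 with the block as well, 0.0662 without uninduced replicate 3, and 0.0556 after centring each array. The 8 genes of protein folding in the endoplasmic reticulum did not pass the list test (median 0.13, 0.22 and 0.06 in the runs, adjusted p = 0.478, 0.328 with the block), though fry with the block, which does not compare a list with other genes, gave an adjusted p of 0.0239. The 2 measured laccases of 17 listed, LAC16 and AT5G01050 (-0.28 ± 0.19), were not tested as a list. Adjusted over the list alone, 0 genes of the DNA replication and protein folding lists changed.

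**Figure D3:**
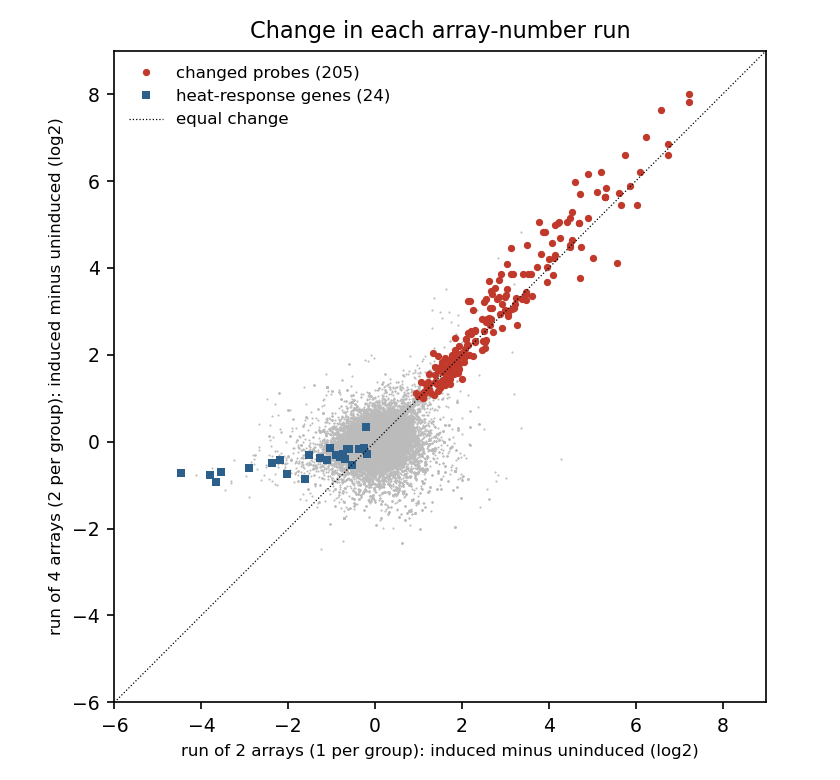
Change of each probe, induced minus uninduced on a log2 scale, in the run of 2 arrays (horizontal axis, 1 array per group) and in the run of 4 arrays (vertical axis, 2 arrays per group). Red circles are the 205 changed probes, which lie near the dotted line of equal change. They were chosen on the arrays of both runs, so their place is no independent check. Blue squares are 24 heat-response genes, whose median was -1.07 in the run of 2 and -0.38 in the run of 4.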

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

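All alternatives with the run of 4 arrays alone, combined settings, single-gene probes or identical rows, and all those of the added lists, the heat-response list and the families (except the estimated correlation for families), were chosen after the data were seen. Every list test, and the tests of the families EXPA, TBL and PRA, kept their direction under every alternative run, and the direction of the other families was not compared. No cause was tested for the changes below, except that fewer arrays or probes enter some fits by construction. Higher and lower probes (205 and 0 as reported) numbered 351 and 14 with trend and robust estimation, 318 and 5 after quantile normalization, 381 and 13 with the run as a block, and 457 and 28 with array weights. They numbered 802 and 423 with trend, robust estimation and the block, 378 and 7 with quantile normalization and the block, and 878 and 329 with all of these. Higher probes were 86 at an adjusted p under 0.01, 119 with treat, which tests against a minimum change, and 106 over single-gene probes. Lower probes were 1 without the dimmest 25%, 1 with identical rows counted once, 3 in the run of 4 and 21 with the unmoderated test. Leaving out 1 array gave 56 to 154 higher and 0 lower. With an estimated correlation, adjusted p was 0.0620 for cell cycle, 0.474 for class III peroxidases, 0.129 for genes co-expressed with secondary wall synthesis and for mitosis, 0.294 for DNA replication and ribosomal proteins, 0.0675 for heat response, and 0.938 for the families EXPA, TBL and PRA. With an estimated correlation and the block together it was 0.0920 for xylan, lignin polymerisation and cell cycle, 0.0697 for autolysis, 0.147 for primary wall, 0.196 for class III peroxidases, 0.0585 for mitosis, 0.172 for DNA replication and ribosomal proteins, 0.179 for heat response and 0.5846 for the 3 families. With fry, which does not compare a list with other genes, it was 0.0972 for class III peroxidases, 0.0976 for DNA replication and 0.150 for ribosomal proteins. With fry and the block together these were 0.00213, 0.00523 and 0.0230, while protein folding passed at 0.0239 (0.478 as reported) and heat response missed at 0.0574 (0.0331 by fry without the block). Centring on the median gave 0.0611 for primary wall, 0.0556 for DNA replication and 0.0632 for EXPA and PRA, and quantile normalization 0.0808 for EXPA. In the run of 4 alone it was 0.0571 for class III peroxidases and DNA replication, 0.0794 for EXPA, 0.0912 for PRA and 0.103 for TBL. With 1 array left out, adjusted p ranged from 3.1e-04 to 0.0769 for primary wall, 0.0196 to 0.0662 for DNA replication, 0.00239 to 0.0625 for EXPA and for TBL, and 0.00770 to 0.0625 for PRA. The other list results stayed on their side of the threshold under the remaining alternatives. Of 92 named genes, 29 passed the threshold: 16 of these lost it without at least 1 array and 6 under another alternative, and 8 of the other 63 passed it under some alternative. No named gene that passed changed sign. The alternatives for the VND1 level and the VND family comparison gave no value. The number of arrays limits the precision.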

Other observations

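The tests of the run and of the normalization as sources of the asymmetry, the test of induced replicate 1, the tests without members seen beforehand, and the heat-response list itself were chosen after the results were seen. The medians of the mitosis and ribosomal protein lists had been seen before they were set against random lists.

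Among 34 families of genes sharing a symbol stem, 3 were higher in induced cells by camera at the preset correlation, with small median changes. EXPA (13 expansins, which loosen the wall) had a median of 0.26 (camera adjusted p = 0.00509). TBL (23 wall acetyltransferases and relatives) had 0.13 and PRA 0.16 (camera adjusted p = 0.00913 for each). With an estimated correlation the adjusted p was 0.938 for each. In the TBL family TBL33 and TBL34 rose, while TBL31 (2.49 ± 0.39 on the log2 scale, SE) and TBL45 (0.98 ± 0.28) did not pass the test. TBL31, TBL33 and TBL34 are also in the xylan list, so this family is not separate evidence. TBL36, named after its value was seen, gave -0.75 ± 0.18 (adjusted p = 0.449), and was lower with the run as a block (adjusted p = 0.0318) and with array weights (0.0339). No EXPA or PRA gene passed the test. EXPA22 gave 0.50 ± 0.22 and EXPA15 0.45 ± 0.17, and of the PRA family, which acts in membrane traffic, PRA1.B5 gave 0.76 ± 0.15 and PRA1.B4 0.49 ± 0.13.

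Several changed genes outside the rule for naming, chosen here after their values were seen, code for proteins of sugar transport, the cytoskeleton, lignin and acetyl-CoA supply. AT2G28315, a transporter of UDP-xylose, the building block of xylan, rose 22.8-fold (adjusted p = 6.2e-04, all 3 induced arrays above all uninduced ones). AT3G14170 and TRM30, both related to cortical microtubules, rose 15.2-fold (adjusted p = 5.1e-04) and 16.1-fold (adjusted p = 0.0176). AT2G43120 (PIRIN2), which affects lignin composition, rose 2.35-fold (adjusted p = 0.0406). ACLA-2, a subunit of ATP-citrate lyase, rose 3.89-fold (adjusted p = 0.0155). The calls of AT2G28315 and AT3G14170 held whichever array was left out. Those of PIRIN2 and ACLA-2 were lost whichever array was left out (adjusted p up to 0.291 and 0.120) and in the run of 4 arrays alone (0.0777 and 0.0867). The PIRIN2 call was also lost after centring each array on its median (0.0995). The TRM30 call was lost for 5 of the 6 arrays left out (up to 0.134). The 5 probes with the largest rises without a gene in the annotation used rose by 6.31 to 7.75 on the log2 scale.

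Far more probes passed the adjusted threshold as higher than as lower after induction, at 205 and 0. At an unadjusted p under 0.05 limma gave 1151 higher and 1053 lower, so the asymmetry concerns the called probes. The 6 arrays give only 10 splits into 3 and 3, too few for a share under 0.05; only 1 of the 10, the real one, gave as many changed probes, with 205 against at most 0 in the others. Quantile normalization brought out few falls: 5 against 318 rises without a block, which is 1.55% of changed probes against 0% in the deposited values. With the run as a block falls made up 1.82% against 3.30% (27.3% against 34.5% with a variance trend and robust estimation as well). Aligning the arrays to 1 distribution thus did not raise the share of falls in the fits with the block. Quantile normalization itself assumes that all arrays share 1 distribution, so it cannot show falls hidden by a shift that breaks this. The authors' normalization therefore stays open as a source of the asymmetry. Fewer falls passed the threshold when the run was left out of the fit, at 0 against 13 with the block. Several of these 13 probes share all 6 values with each other, so the 13 and the 3.30% count 1 measurement more than once. With a variance trend and robust estimation falls numbered 14 without the block and 423 with it. Rises increased as well, from 205 to 381 and from 351 to 802. How much of the asymmetry the difference between the runs explains stays open. Falls made up 3.30% of changed probes with the block alone, but 34.5% with the block, a variance trend and robust estimation. Simulated rises and falls of equal size were found about equally often, but the simulation set no lower limit on probe levels. It cannot say whether falls of probes near background were harder to find than rises. An effect of VND1 as an activator is a biological explanation that these tables do not test apart from estrogen.

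Heat-response genes lay lower in induced cells. Of 24 measured genes 23 were negative, with a median of -0.59, none passing the test. The largest were AT1G52560 (-1.98 ± 0.92, SE) and AT1G71000 (-1.84 ± 0.67). The list was lower by camera (p = 2.6e-15, 2.1e-10 with the run as a block), but p was 0.0675 with an estimated correlation and 0.179 with the block as well. By fry p was 0.0331, and 0.0574 with the block.

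The lower values were not confined to induced replicate 1. In the run of 4 arrays, without it, 23 of the 24 genes were negative. The list's mean there was -0.41 (95% interval over genes -0.53 to -0.29). That run has 2 arrays per group, so a chance difference between those arrays stays open. Without 6 members whose values had been seen before the list was written, the mean of the other 18 in that run was -0.33 (-0.45 to -0.21). The 18 still include AT2G29500, which is among the largest falls of named genes (-1.37, and -0.60 in the run of 4). They also belong to the same stress program as the 6, so they are no independent check. The mean of all 24 in the run of 2 arrays was -1.56 (-2.10 to -1.02 over genes). Camera on the difference between the runs gave p = 5.1e-23 for the list, and 0.0434 with an estimated correlation, while 0 single probes had such a difference at an adjusted p under 0.05. The run of 2 has 1 array per group, so the spread in that test comes from the run of 4 alone, and how far the larger shift belongs to 1 array or to chance stays open. The median of -0.38 in the run of 4 lay below the lowest of 10000 random lists matched on mean expression (-0.21). The median of -0.32 of the 18 genes left after removing the 6 also lay below the lowest of its random lists. A shift common to genes of the same expression level does not predict this. However, some members were listed after their falls had been seen, so unselected random lists are not a fair measure for the list. Whether the induction of VND1, the estrogen or the handling of the cultures could be the source cannot be told apart, as 0 groups of estrogen-treated cells without the construct are among the 6 arrays. The genes of one stress program move together, so an interval over genes is narrower than one over cultures would be.

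Mitosis and ribosomal protein genes were slightly lower in induced cells, in both runs. The median of the 17 mitosis genes was -0.37 and that of the 101 ribosomal protein genes -0.17. Neither is what a shift common to genes of the same expression level predicts, as the lowest of 10000 matched random lists had medians of -0.29 and -0.11. A candidate explanation is that fewer induced cells were dividing, which may follow from vessel differentiation, but co-regulated genes share the chance differences of a culture and p with an estimated correlation missed the threshold (0.129 and 0.294, adjusted). Estrogen itself and differences in culture growth were not tested and stay open.

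A further hypothesis was that estrogen raised the GSTU glutathione transferases, a family of detoxification enzymes. The mean change of 11 GSTU genes was 0.26 on the log2 scale, with a 95% interval over genes from -0.02 to 0.53, and the upper end in the run of 2 arrays was 0.74. Camera gave p = 0.0216 (adjusted p = 0.0814 over 34 families), 0.0137 with the run as a block, and 0.423 with an estimated correlation. A camera p under 0.05 had been set beforehand as the sign of a rise and an upper end under 0.58 as the sign of none. Both were met, so the test does not decide, and the hypothesis stays open.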
